A study of Mus musculus with 16 samples.

How the data were processed

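Messenger RNA was sequenced from NIP-binding, IgD-negative, CD38-positive splenic B cells that lacked the germinal center markers GL7 and FAS and the plasma cell marker CD138. The mice were C57BL/6 and carried a Zfp318 reporter allele (ZSDAT) with a tdTomato fluorophore, AID-Cre and the B1-8hi heavy chain. Cells were taken 7 days after immunization with NP-OVA, LPS and alum, and libraries of about 1000 cells were made with Smart-seq2, per the labels' protocols. The libraries fell into 4 groups of 4. HetTN and HetTP were the tdTomato-negative and tdTomato-positive cells of mice heterozygous for the allele, and KOTN and KOTP were those of homozygous mice.

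Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned to mm10 with STAR 2.2.0 and counted with featureCounts. Neither the strand setting nor the handling of read pairs is stated there. The authors deposited 1 table per genotype, each with raw counts over coding sequence per the file headers. The deposited RPM columns hold per-million counts of mapped reads, made by the authors with 1 divisor per library, per the file headers. In the heterozygous table the deposited counts amounted to between 1.35 and 1.5 per mapped read in the divisor. In the homozygous table they amounted to between 0.369 and 0.419. A value above 1 means that the divisor or the raw counts were not made as for a plain RPM. Which of these holds is not stated, so the raw counts may also have been made differently in the tables. The authors also deposited a log2 ratio of the group means of the per-million columns, with an offset of 1 in the heterozygous and 0.1 in the homozygous table. Neither the per-million columns nor the deposited log2 ratios were used in a test here.

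From the deposited counts, the 22680 entries of each table were joined on the gene symbol, leaving out the 4 entries per table of 2 duplicated names and 1 name per table without a partner, which gave 22675 genes. Symbols matched GENCODE mouse release M21 for 88.8% of the joined genes, and positions (GRCm38) and coding lengths were taken from it. The total count per library ranged from 7748787 to 15742445. Counts were normalised with TMM, genes were filtered by group with filterByExpr, and 10687 genes were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1), using the robust quasi-likelihood test on group means of all 16 libraries with 12 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, called under 0.05. Expression is given as CPM, the per-million counts of the library total scaled with TMM, and spreads are SD over 4 libraries. The labels do not state that the libraries came from separate animals, so p-values measure the spread between these libraries. Reads carried no molecular identifiers, so counting intervals and the floor of 3 counts over a group cover counting error only. A fold against a group without a count was computed against that floor, and with 1 to 3 counts an exact Poisson interval is given.

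The 5 comparisons were these: tdTomato-positive against tdTomato-negative cells in each genotype, homozygous against heterozygous cells in each sorted population, and the difference of the tdTomato effects between the genotypes. The comparisons, the test, 48 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Lists with at least 3 tested members (47 lists) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. Named genes were Zfp318 and, with a mean log2 CPM of at least 3 and no overlap between the libraries compared, the 10 largest rises and 10 largest falls past the threshold. From each list up to 4 members with the smallest p past the threshold were added. The no-overlap condition did not apply to the difference between the genotypes. Where fewer than 5 genes passed, the 5 with the smallest p were taken. Symbols of predicted genes, clones, pseudogenes and variable segments were left out. Genes of a list that share reads with near-identical copies (light chain constant genes, IgG2 constant genes, MHC class II, histones and mitochondrially encoded genes with nuclear copies) are uncertain, since the handling of reads that map to several places is not stated.

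The alternatives were RLE and upper quartile scaling, no filter, a filter at 5 CPM in at least 4 libraries, DESeq2 1.42.0, limma voom with sample quality weights, a block for the replicate number, a fit of the compared libraries alone, and each replicate left out in turn. After the data were seen, DESeq2, voom and the leave-outs were also run on the compared libraries alone, the rule for named genes was applied to the fit of the 8 homozygous libraries, and 8 antigen receptor genes were added for the genotype comparisons. Each comparison was tested on 1 set of simulated data with 200 changed genes. These data were made from the library totals and from the means and spreads of each genotype, taken over both sorted populations. For the genotype comparisons, the mean of a gene was averaged over the genotypes, so that setting differs from the libraries compared. Each comparison was also refitted over other splits of the same libraries. In simulated data of the heterozygous tdTomato comparison with 10449 genes, the fit of all libraries called 184 genes, of which 138 had not been changed, while the fit of the 8 libraries called 20, with 2 unchanged. In simulated data of the homozygous tdTomato comparison, the fit of the 8 libraries recovered 44.6% of genes changed 1.5-fold, 69.4% of those changed 2-fold and 82% of those changed 4-fold among 9933 genes, with 11 unchanged genes among 140 calls. The fit of all libraries called 34 genes there, none of them unchanged, among 10428. For the genotype comparisons, unchanged genes made up 18 of 63 simulated calls in tdTomato-positive cells and 6 of 47 in tdTomato-negative cells with all libraries, and 11 of 41 and 0 of 23 with the compared libraries alone. Protein levels, surface phenotype and recall responses were not analysed here.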

Results

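The series addressed how antigen-specific memory-phenotype B cells differ when they express Zfp318 or lack it. Zfp318 is a zinc finger protein that is required for IgD expression, since it lets transcription run from the Ighm into the Ighd exons. Gene expression was measured by RNA sequencing of sorted splenic B cells 7 days after immunization, in 16 libraries of about 1000 cells each. The cells bound the hapten NIP, expressed CD38 and lacked surface IgD, GL7, FAS and CD138. They were sorted as tdTomato-positive or tdTomato-negative from mice with 1 or 2 copies of the ZSDAT reporter allele of Zfp318, which gave 4 groups of 4 libraries. Total counts were 8099655, 11640994, 15429025 and 11493829 in heterozygous tdTomato-negative cells and 10709268, 12446314, 15742445 and 13279863 in heterozygous tdTomato-positive cells. They were 7748787, 8977394, 9312153 and 8558990 in homozygous tdTomato-negative cells and 8099503, 7991732, 9238490 and 14325276 in homozygous tdTomato-positive cells.

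The heterozygous libraries varied more than the homozygous ones. The biological coefficient of variation was 0.845 in the heterozygous table and 0.2 in the homozygous table, and the median correlation of log2 CPM within a group was 0.766 and 0.797 against 0.96 and 0.959. Between 7.02% and 13.6% of the tested genes had no count in a heterozygous library, against between 1.52% and 2.34% in a homozygous library. Genotype and deposited table coincided, so a difference of batch or counting between the tables cannot be told apart from genotype. Deposited counts per mapped read were 1.35 to 1.5 in the heterozygous and 0.369 to 0.419 in the homozygous table. The sort excluded surface IgD, which requires Zfp318, so the gate may have kept unlike cells in the genotypes. Such a difference in the cells sorted cannot be told apart from a change within cells.

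Zfp318 (ENSMUSG00000015597, GRCm38 chromosome 17, 46383731 to 46420920, plus strand), the targeted gene, matched the genotype labels in every library. Its level was 71, 153.5, 116.5 and 132.7 CPM in heterozygous tdTomato-negative and 109.8, 83.9, 94.2 and 121.1 CPM in heterozygous tdTomato-positive libraries. It was 5.8, 0.5, 1.5 and 2.2 CPM in homozygous tdTomato-negative and 2.8, 2.9, 0.9 and 1.2 CPM in homozygous tdTomato-positive libraries. Homozygous cells had a log2 fold change of -5.72 (SE 0.55, adjusted p = 3e-06) among tdTomato-positive and -5.60 (SE 0.54, adjusted p = 3.6e-06) among tdTomato-negative cells. Between tdTomato-positive and tdTomato-negative cells Zfp318 did not pass in either genotype, with log2 fold changes of -0.21 (SE 0.43, adjusted p = 0.886) in heterozygous and -0.33 (SE 0.53, adjusted p = 1) in homozygous cells. Ighd (ENSMUSG00000104213, chromosome 12, 113406604 to 113416324, minus strand), the IgD heavy chain, fell from 913 ± 110 to 29.3 ± 10.4 CPM in tdTomato-negative and from 907 ± 153 to 23.6 ± 5.71 CPM in tdTomato-positive cells (SD, n = 4). The log2 fold changes were -4.96 (SE 0.25, adjusted p = 5.8e-10) and -5.26 (SE 0.25, adjusted p = 2.7e-10). Ighm, the IgM heavy chain, fell less, with log2 fold changes of -2.21 and -1.67.

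**Figure D1:**
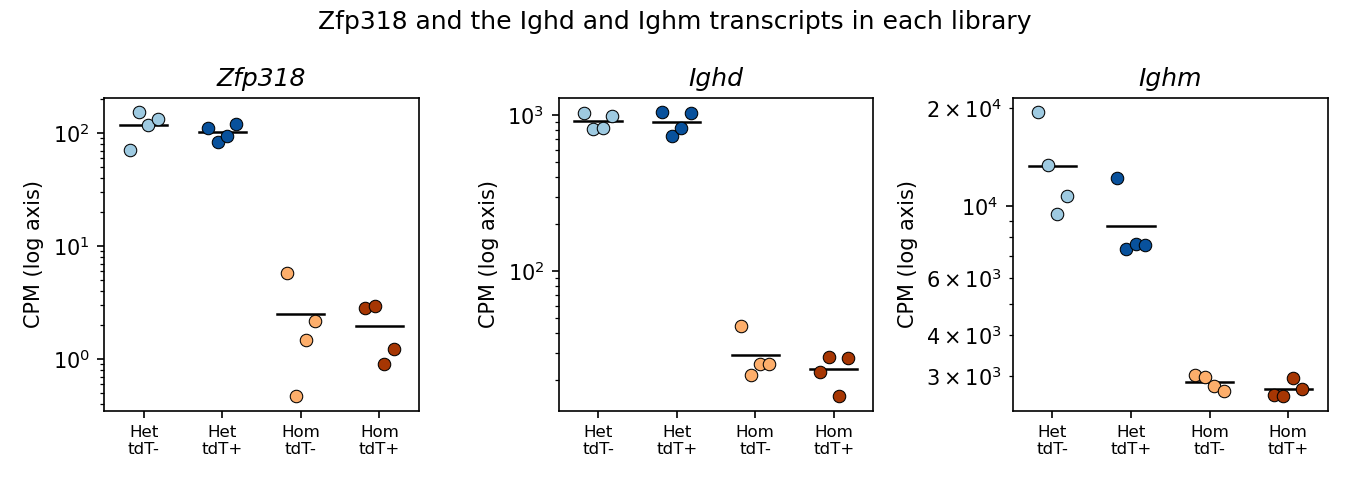
CPM on a log axis of Zfp318, Ighd and Ighm, with 1 point per library, a black line at the mean of each group of 4 and the groups along the x axis (Het, heterozygous; Hom, homozygous; tdT, tdTomato). Every homozygous library lay below every heterozygous library for Zfp318, where the homozygous values reached 5.8 CPM and the heterozygous ones began at 71 CPM.

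The comparison of homozygous with heterozygous tdTomato-positive cells asked how sorted cells with an active reporter differ between the genotypes. Homozygous cells expressed more of the chemokine receptors Ccr6, 826 ± 15 against 164 ± 23.2 CPM, and Cxcr3, 544 ± 25.4 against 44.8 ± 24.5 CPM (SD, n = 4 per group). They held more Iglc1, the lambda 1 light chain, at 11800 ± 187 against 1530 ± 369 CPM, and more Ighg2b, an IgG heavy chain, at 1570 ± 77.9 against 290 ± 140 CPM. They held less of the germinal center regulator Bcl6, 58.3 ± 10.4 against 199 ± 39.9 CPM, and of Jchain, which joins IgM and IgA polymers, 6.28 ± 1.04 against 137 ± 48.8 CPM. With edgeR's quasi-likelihood test, 1099 of 10687 genes passed an adjusted p of 0.05, of which 541 were higher and 558 lower in homozygous cells. The fit of the 8 libraries compared called 1182 genes, 943 of them shared. Leaving out homozygous tdTomato-positive library 4 gave 722, and without library 1, 2, 3 or 4 of that group the 8-library fit gave 718, 661, 630 and 631. Without heterozygous tdTomato-positive library 1, 2, 3 or 4 the 8-library fit gave more calls, 1475, 1416, 1399 and 1314. Both fits share the spread of a gene between the more variable heterozygous and the less variable homozygous libraries, so the counts depend on this shared estimate. With upper quartile scaling 59.6% of the calls were higher, against 49.2% with TMM.

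The largest rises included Cxcr3 (3.60, adjusted p = 0.0005), Iglc1 (2.95, adjusted p = 3.4e-10), the atypical chemokine receptor Ackr2 (2.79), Ighg2b (2.43), Ccr6 (2.33, adjusted p = 3.2e-08) and Cdk5rap1 (2.28), all as log2 fold changes. Tbx21, which encodes T-bet, rose by 3.06 (adjusted p = 0.0163), but the fit of the 8 libraries gave adjusted p = 0.0501. Among the largest falls were Ighd, the heme oxygenase Hmox1 (-5.02), Gcsam, a germinal center signaling protein (-4.56), Jchain (-4.44), the adhesion molecule Vcam1 (-4.25), Fcna (-4.22), Rnf44 (-4.03) and the splicing factor Sf3a2 (-4.01). Trac (ENSMUSG00000076928, chromosome 14, 54220521 to 54224206), the T cell receptor alpha constant region, had 2 counts in homozygous against 15350 in heterozygous tdTomato-positive libraries, a 4970-fold difference with a counting interval of 1380 to 41100.

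Genes of cell division were lower in homozygous tdTomato-positive cells. Of 37 genes of G1/S and DNA replication, 26 fell and none rose, and 31 fell when adjusted over the list alone. The replicative helicase subunits Mcm5 (-2.21) and Mcm3 (-1.87) fell. Of 38 genes of G2/M and mitosis, 22 fell, or 27 when adjusted over the list alone, including the proliferation marker Mki67 (-2.01), the mitotic activator Cdc20 (-2.88) and the checkpoint kinase Bub1b (-2.21). Of 18 germinal center genes, 9 fell and none rose, 10 when adjusted over the list alone. They included Gcsam, Mef2b (-2.43), a transcription factor upstream of Bcl6, Neil1 (-2.09) and Bcl6 (-1.77). The camera adjusted p was 6.2e-23 for G1/S, 9.7e-17 for G2/M and 5.8e-10 for germinal center genes. With an estimated correlation, the adjusted p was 0.00605 for G1/S, 0.156 for G2/M and 0.0115 for germinal center genes. In the fit of the 8 libraries compared, no list held with an estimated correlation, with an adjusted p = 0.207 for both G1/S and germinal center genes. T cell markers moved the same way, with 3 of 8 lower (5 adjusted over the list alone) and a median of -3.64 with genes without counts at their bound (camera adjusted p = 4.9e-05, adjusted p = 0.156 with an estimated correlation). Of 12 myeloid markers 5 were lower and 1 higher, over all genes and adjusted over the list alone, with C1qc at -3.63 and C1qb at -3.86 (camera adjusted p = 0.00435, adjusted p = 0.394 with an estimated correlation).

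Ribosomal and antigen presentation genes were higher. Of 82 genes of the cytosolic ribosome, 67 rose and none fell, 75 when adjusted over the list alone, with Rpl19 at 1.01 and Rps13 at 0.99 (camera adjusted p = 5.2e-22, adjusted p = 0.373 with an estimated correlation). Of 18 genes of MHC class II and antigen presentation, 12 rose and 3 fell, the same counts when adjusted over the list alone. H2-Eb1 (0.92) and H2-Ab1 (0.95) encode class II beta chains, and H2-Oa (1.00) and H2-Ob (1.12) modulate peptide loading (camera adjusted p = 6.1e-06, adjusted p = 0.156 with an estimated correlation). Of 12 genes of CD11c-positive T-bet-positive B cells, 3 rose, 6 when adjusted over the list alone, among them Cxcr3, Tbx21 and the inhibitory receptor Cd72 (0.85; camera adjusted p = 0.00191, adjusted p = 0.0405 with an estimated correlation, 0.225 in the 8-library fit). Of 21 chemokine, S1P and homing receptors, 4 rose and 1 fell, 5 and 1 when adjusted over the list alone. They included Gpr183, an oxysterol receptor that positions B cells (1.88; camera adjusted p = 0.00734, adjusted p = 0.156 with an estimated correlation). Of 23 memory B cell markers, 5 rose and 2 fell, 7 and 2 when adjusted over the list alone, with Cd38 at 1.62 and the quiescence factor Klf2 at -1.42 (camera adjusted p = 0.0272, adjusted p = 0.231 with an estimated correlation).

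Of 38 genes of MYC and ribosome biogenesis, 10 fell over all genes and adjusted over the list alone, among them Fbl (-1.13) and Pa2g4 (-1.07; camera adjusted p = 5.5e-06, adjusted p = 0.156 with an estimated correlation). Of 39 B cell transcription regulators, 2 rose and 9 fell, 4 and 10 when adjusted over the list alone, with Mybl2 at -2.68 and Tcf3 at -1.84 (camera adjusted p = 0.0144, adjusted p = 0.229 with an estimated correlation). Immediate early, cholesterol synthesis, dendritic cell and histone lists also passed, with camera adjusted p = 0.0185, 0.0278, 0.0185 and 0.0174, and adjusted p = 0.229, 0.229, 0.156 and 0.293 with an estimated correlation. These lists moved both ways, with medians of -0.94 for immediate early and 0.70 for histone genes. Their members included Zfp36 (-1.59), an mRNA decay factor, the antiproliferative gene Btg2 (1.53), and the sterol enzymes Sqle (-1.90) and Cyp51 (-1.64).

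The comparison of homozygous with heterozygous tdTomato-negative cells asked the same of cells without reporter signal. Homozygous cells expressed more Cxcr3, 650 ± 57.7 against 43.9 ± 35.8 CPM, more Tbx21, 172 ± 7.69 against 11.9 ± 6.98 CPM, and more Ccr6, 695 ± 57.2 against 182 ± 41.1 CPM (SD, n = 4 per group). They held less Bcl6, 84.7 ± 17.4 against 318 ± 79.1 CPM, and less Fcmr, the IgM Fc receptor, 1020 ± 22.2 against 2460 ± 295 CPM. Here 1121 of 10687 genes passed in edgeR's test, 600 higher and 521 lower, against 724 in the fit of the 8 libraries compared, with 681 shared. Leaving out homozygous tdTomato-negative library 1, 2, 3 or 4 gave 728, 632, 608 and 629 calls, and 330, 238, 240 and 247 in the 8-library fit. Leaving out heterozygous tdTomato-negative library 1, 2, 3 or 4 in the 8-library fit gave more, 1086, 942, 894 and 1073. With upper quartile scaling 63.5% of the calls were higher, against 53.5% with TMM.

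The largest rises in tdTomato-negative cells included the nucleic acid sensors Tlr9 (4.69, adjusted p = 0.00574) and Tlr3 (4.43, adjusted p = 0.0182), Cxcr3 (3.88) and Tbx21 (3.84, adjusted p = 0.00584). Tlr9 did not pass with voom and sample weights (adjusted p = 0.067). Itgax, the integrin CD11c, had 2 counts in heterozygous and 1030 in homozygous tdTomato-negative libraries, a 732-fold difference with a counting interval of 203 to 6050. The B1 cell markers Spn and Cd5 were 920-fold (165 to 36300) and at least 84.9-fold higher. Between 11.7% and 13.6% of tested genes had no count in a heterozygous tdTomato-negative library, against 1.52% to 1.73% in a homozygous one. Missed weak transcripts therefore cannot be told apart from low expression in these 3 folds, and the counting intervals do not cover this. Trac was at least 3010-fold lower, with no count in homozygous against 12837 in heterozygous tdTomato-negative libraries. Other falls included the complement genes C1qc (-5.07), C1qa (-4.23) and C1qb (-4.07), with Vcam1 (-4.64), Sf3a2 (-4.08), Fcna (-4.01) and Hmox1 (-3.99).

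Of 12 genes of CD11c-positive T-bet-positive B cells, 8 rose in homozygous tdTomato-negative cells and none fell, 8 also when adjusted over the list alone. Besides Itgax, Tbx21 and Cxcr3 they included Fcrl5, an inhibitory Fc receptor-like protein (1.73), and the integrin Itgb1 (1.96; camera adjusted p = 2.6e-08, adjusted p = 0.00194 with an estimated correlation). Of 13 marginal zone and B1 cell genes 6 rose, 7 when adjusted over the list alone (camera adjusted p = 0.00678, adjusted p = 0.154 with an estimated correlation). Of 21 chemokine, S1P and homing receptors, 8 rose and 1 fell, 9 and 1 when adjusted over the list alone, with Gpr183 at 1.66 (camera adjusted p = 0.00161, adjusted p = 0.133 with an estimated correlation). Of 18 naive follicular genes, 5 rose and 7 fell, with the same counts when adjusted over the list alone. Among those that fell were Ighd, Klf2 (-1.54) and Fcmr (-1.27, adjusted p = 6.3e-07; list camera adjusted p = 0.00504, adjusted p = 0.326 with an estimated correlation).

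Cell division genes fell in tdTomato-negative cells too. Of 37 G1/S genes 17 fell, 24 when adjusted over the list alone, with Mcm5 at -1.56 and Pcna, the polymerase clamp, at -1.13 (camera adjusted p = 1.9e-13, adjusted p = 0.0269 with an estimated correlation). Of 38 G2/M genes 14 fell, 20 when adjusted over the list alone, with Mki67 at -1.52 and the topoisomerase Top2a at -1.45 (camera adjusted p = 5.6e-10, adjusted p = 0.326 with an estimated correlation). Of 18 germinal center genes 5 fell, 7 when adjusted over the list alone, including Bcl6 (-1.91), Mef2b (-1.51) and Ezh2, a histone methyltransferase (-1.07; camera adjusted p = 0.00504, adjusted p = 0.189 with an estimated correlation). Of 20 plasma cell genes, 1 rose and 4 fell, 1 and 5 when adjusted over the list alone, with Jchain at -2.78 and Tnfrsf13b, the receptor TACI, at 1.44 (camera adjusted p = 0.0259, adjusted p = 0.411 with an estimated correlation). T cell markers moved with these groups, with 3 of 8 lower (4 adjusted over the list alone) and a median of -4.47 with genes without counts at their bound (camera adjusted p = 2.1e-05, adjusted p = 0.133 with an estimated correlation). Of 12 myeloid markers 7 were lower, or 9 lower and 1 higher when adjusted over the list alone (camera adjusted p = 4.2e-05, adjusted p = 0.236 with an estimated correlation).

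All 11 passing members of the 13 mitochondrially encoded genes fell in tdTomato-negative cells, 11 also when adjusted over the list alone. They included mt-Nd6 (-2.83, adjusted p = 6.7e-06), mt-Nd2 (-1.81) and mt-Nd1 (-1.34), all subunits of respiratory complex I (camera adjusted p = 7.8e-13, adjusted p = 0.151 with an estimated correlation). Of 82 ribosomal genes 33 rose and none fell, or 64 rose and 1 fell when adjusted over the list alone, with Rpl37a at 1.03 and Rpl19 at 0.62 (camera adjusted p = 1.2e-09, adjusted p = 0.623 with an estimated correlation). Of 18 antigen presentation genes 11 rose and 2 fell, 12 and 3 when adjusted over the list alone. The reductase Ifi30 (1.57), H2-Oa (0.93) and H2-Eb1 (0.68) were higher and the invariant chain Cd74 was lower (-0.84, adjusted p = 4.8e-05; list camera adjusted p = 0.00762, adjusted p = 0.411 with an estimated correlation). Lists of MYC targets, ATF4 targets, dendritic cell markers and histones also passed, with camera adjusted p = 0.0301, 0.00815, 0.00504 and 0.00188, and adjusted p = 0.589, 0.189, 0.0984 and 0.189 with an estimated correlation. Of the 17 lists that passed, 7 were higher and 10 lower in homozygous cells, with dendritic cell markers and histones at medians of 2.62 and 0.80. The remaining 30 of 47 lists did not pass in tdTomato-negative cells, nor did 31 in tdTomato-positive cells.

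**Figure D2:**
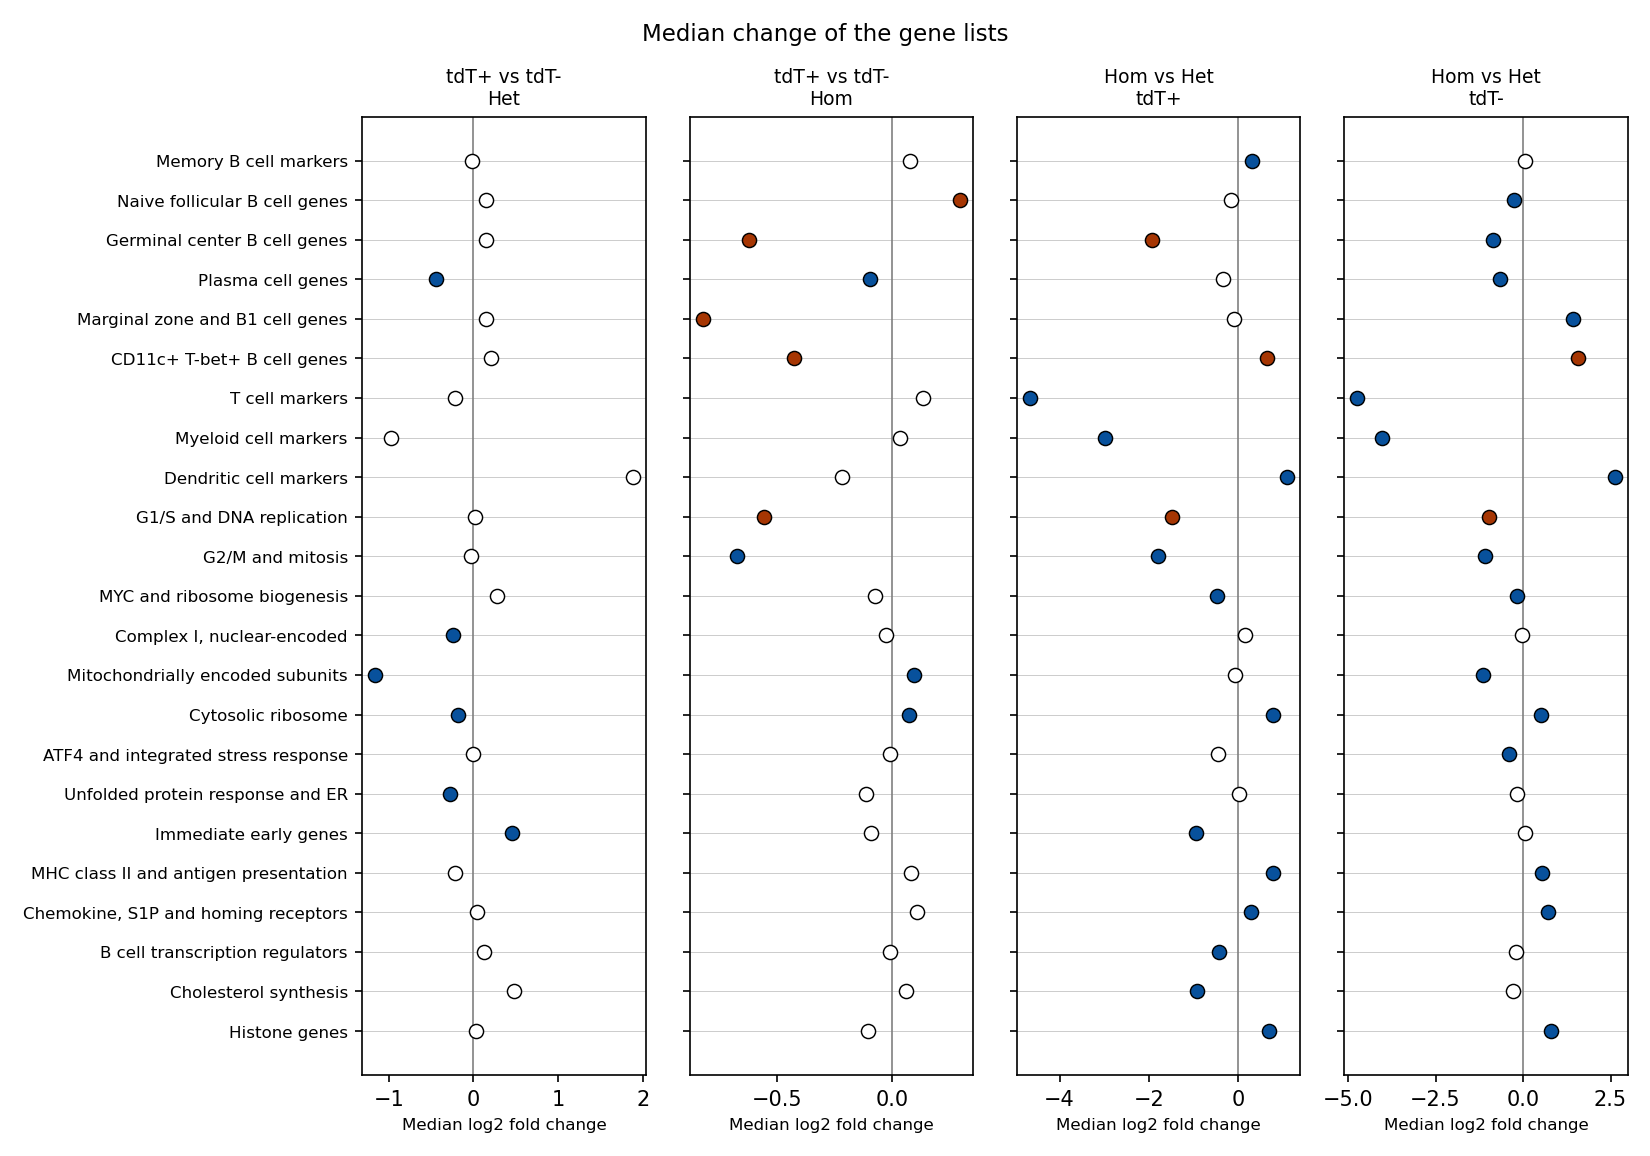
Median log2 fold change of each gene list that passed in at least 1 comparison (y axis, lists; x axis, median; 1 panel per comparison), with blue points for lists that passed the camera test, brown for those that also passed with an estimated correlation and white for those that did not pass. In the panels of homozygous against heterozygous cells, G1/S genes lay at -1.48 in tdTomato-positive and -0.99 in tdTomato-negative cells, and ribosomal genes at 0.79 and 0.51.

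The genotype differences of the sorted populations overlapped. Of the genes higher in homozygous cells, 245 were called in both populations, against 30.4 for independent lists of that size, and of those lower 291, against 27.2. Only 2 genes were called in opposite directions. Both comparisons set the same 2 deposited tables against each other, so a difference between the tables would also give such an overlap. The populations share no library, and the log2 fold changes correlated across genes with Pearson's r = 0.414 and Spearman's rho = 0.426, although genes are not independent replicates. Genes called in both included Zfp318, Ighd, Ccr6, Cxcr3, Gpr183, Cd38, Bcl6, Mki67, Hmox1 and Trac.

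The reporter is part of the Zfp318 allele, but Zfp318 transcripts did not pass between tdTomato-positive and tdTomato-negative cells in either genotype. In homozygous mice, where little Zfp318 transcript was found, tdTomato-positive cells were compared with tdTomato-negative cells. The tdTomato-positive cells expressed more Fcmr, 1610 ± 70 against 1020 ± 22.2 CPM, and more Cd55, a complement regulator, 293 ± 31.9 against 177 ± 4.25 CPM (SD, n = 4 per group). They expressed less Jchain, 6.28 ± 1.04 against 50.4 ± 36.2 CPM, less Gcsam, 1.58 ± 1.05 against 11.4 ± 3.4 CPM, and less Tbx21, 100 ± 8.26 against 172 ± 7.69 CPM. In the edgeR fit of all 16 libraries, whose shared spread includes the variable heterozygous libraries, 2 genes passed, with 167 at an unadjusted p under 0.05. These were Fcmr (ENSMUSG00000042474, chromosome 1, 130865669 to 130880791; log2 fold change 0.67, SE 0.10, adjusted p = 0.0447) and Jchain (ENSMUSG00000067149, chromosome 5, 88519809 to 88527891; -3.003, SE 0.49, adjusted p = 0.0472). Leaving out 1 of the 8 homozygous libraries gave 0 calls except without tdTomato-negative library 1, which gave 1. DESeq2 called 11 genes and voom 338. In the edgeR fit of the 8 homozygous libraries alone, 236 of 9974 genes passed, 89 higher and 147 lower. Fcmr was among these 236 genes and Jchain was not. Leaving out homozygous tdTomato-negative library 1 there gave 396 calls, library 2 gave 128 and library 4 gave 148.

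The genes in the next sentences were taken from the fit of the 8 homozygous libraries by the same rule, after the data were seen. Rises included the kinase Lrrk2 (0.81, adjusted p = 2e-05), Cd55 (0.74, adjusted p = 3.3e-06), Fcmr (0.68, adjusted p = 1.3e-07), the IgE receptor CD23, Fcer2a (0.66), the integrin Itgb7 (0.60), the inhibitory receptor Btla (0.56), Id3 (0.50), Glcci1 (0.91) and Scn4a (1.43). Falls included Ptgr1 (-1.75, adjusted p = 2.7e-07), Asb2 (-1.26, adjusted p = 2.3e-09), Tlr3 (-1.38), Marcks (-1.40), Id2, an inhibitor of E proteins (-0.84), the IgG heavy chain Ighg2c (-0.73), the inhibitory Fc receptor Fcgr2b (-0.51) and the tetraspanin Cd81 (-0.59, adjusted p = 8.6e-06). Each of these was called in the 8-library fit without any 1 of its libraries. None of them except Fcmr passed in the fit of all 16 libraries.

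By the list test, naive follicular genes were higher, and germinal center, marginal zone and B1, CD11c-positive T-bet-positive and cell division genes lower, in tdTomato-positive homozygous cells. G2/M genes were lost with an estimated correlation (adjusted p = 0.14), and naive follicular genes in the fit of the 8 libraries with it (adjusted p = 0.134). Of 18 naive follicular genes, 7 rose in the fit of the 8 libraries, or 9 rose and 1 fell when adjusted over the list alone. In the fit of all 16 libraries 1 rose, 5 when adjusted over the list alone (camera adjusted p = 1.7e-12, adjusted p = 0.0112 with an estimated correlation). Of 17 germinal center genes in the 8-library fit, 6 fell, 11 when adjusted over the list alone, including Gcsam (-2.80), Mef2b (-1.16), Cdkn3 (-1.19) and Neil1 (-0.85). Of 13 marginal zone and B1 genes 6 fell, 11 when adjusted over the list alone, including Asb2, the scavenger receptor Cd36 (-0.83), the repressor Zbtb32 (-1.05) and S1pr3 (-0.81). Of 12 genes of CD11c-positive T-bet-positive cells 5 fell, 7 when adjusted over the list alone, including Itgax (-1.18), Tbx21 (-0.76) and Fcrl5 (-0.45). Of 37 G1/S genes 9 fell, 20 when adjusted over the list alone, with Lig1, a DNA ligase, at -0.84 and Mcm5 at -0.74. Of 38 G2/M genes 10 fell, 25 when adjusted over the list alone, with the kinetochore gene Nuf2 at -1.45 and Mki67 at -0.65.

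In the fit of all 16 libraries the camera adjusted p was 1e-14 for germinal center, 7.1e-13 for marginal zone and B1, 1.2e-07 for CD11c-positive T-bet-positive, 6.3e-20 for G1/S and 4e-20 for G2/M genes. The first 4 of these held with an estimated correlation (adjusted p = 0.0013, 0.0013, 0.0013 and 0.00297). Plasma cell, mitochondrially encoded and ribosomal genes also passed (camera adjusted p = 0.00309, 0.0206 and 0.0206), with an adjusted p = 0.343, 0.745 and 0.852 with an estimated correlation. Of the 9 lists that passed, 3 were higher and 6 lower in tdTomato-positive cells. The other 38 of 47 lists did not pass.

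**Figure D3:**
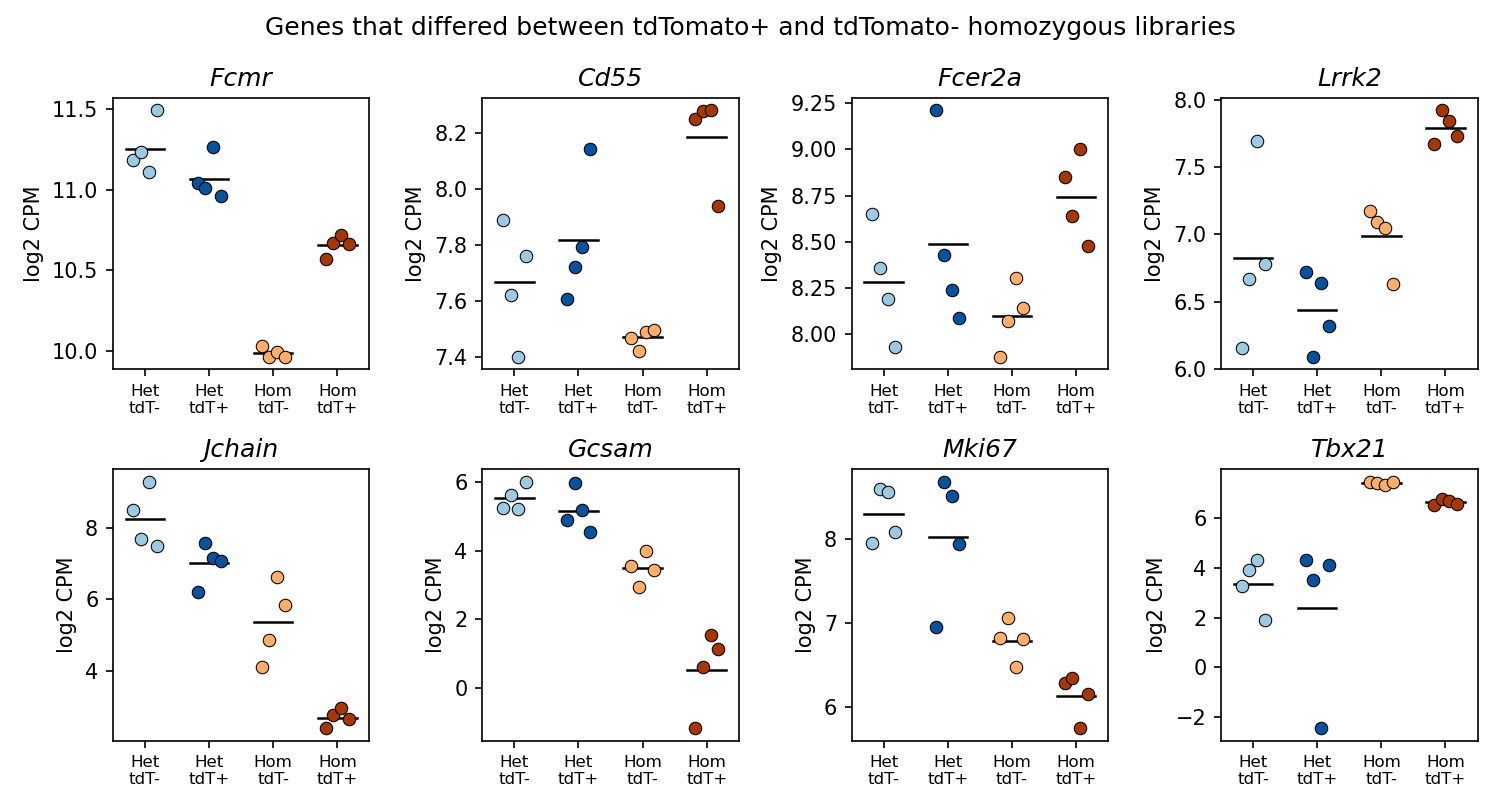
Log2 CPM (y axis) of 8 genes in each library, with 1 point per library, a black line at the mean of each group of 4 and the groups along the x axis (Het, heterozygous; Hom, homozygous; tdT, tdTomato). Fcmr, Cd55, Fcer2a and Lrrk2 lay higher and Jchain, Gcsam, Mki67 and Tbx21 lower in homozygous tdTomato-positive than in homozygous tdTomato-negative libraries, with mean Fcmr levels of 1610 and 1020 CPM.

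In heterozygous mice, tdTomato-positive cells were compared with tdTomato-negative cells, where 1 intact Zfp318 copy remained. Mitochondrially encoded transcripts were lower in tdTomato-positive cells, with mt-Nd1 at 2610 ± 736 against 6030 ± 1270 CPM and mt-Nd2 at 341 ± 123 against 1020 ± 310 CPM (SD, n = 4 per group). Their share of all counts was 1.27%, 2.42%, 2.6% and 1.86% in tdTomato-positive and 3.74%, 2.65%, 4.26% and 3.83% in tdTomato-negative libraries. In edgeR's test 114 genes passed in the fit of all 16 libraries, 64 higher and 50 lower. None passed in the edgeR fit of the 8 heterozygous libraries, where 487 of 9703 genes had an unadjusted p under 0.05, while DESeq2 called 38 and voom 0 in those libraries. Chance cannot be excluded for the 114 calls, since another grouping of the same 8 libraries gave 268. Leaving out tdTomato-negative library 1, 2 or 4, or tdTomato-positive library 3, gave 488, 205, 208 and 209 calls.

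Among the calls of the fit of all 16 libraries, the kinase Mapk9 (2.85, adjusted p = 0.0137), the semaphorin receptor Plxnc1 (2.18, adjusted p = 0.00458), the transcription factor Spib (1.40), the survival factor Mcl1 (0.91) and the follicle homing receptor Cxcr5 (0.86) were higher in tdTomato-positive cells. Itgax was 251-fold higher, with a counting interval of 69.3 to 2070, on 2 against 612 counts. Lower genes included Gtpbp8 (-2.76), Nucb2 (-1.49), the neonatal Fc receptor Fcgrt (-1.35), Mzb1, a plasma cell chaperone (-0.83), H2-DMb1, which aids peptide loading (-0.66), and H2-Ab1 (-0.45). Of 13 mitochondrially encoded genes 6 fell, 11 when adjusted over the list alone, with mt-Nd2 at -1.57, mt-Nd6 at -1.50, mt-Nd1 at -1.21 and mt-Co1 at -1.05 (camera adjusted p = 5.4e-13, adjusted p = 0.631 with an estimated correlation). Lists of nuclear complex I, ribosomal, plasma cell, endoplasmic reticulum and immediate early genes also passed, with camera adjusted p = 0.000821, 0.00798, 0.0461, 0.0461 and 0.0475. None of these held with an estimated correlation, where ribosomal genes had an adjusted p = 0.824 and the other 4 lists an adjusted p = 0.631. Of the 6 lists that passed, 1 was higher and 5 lower in tdTomato-positive cells, and immediate early genes had a median of 0.45. The other 41 of 47 lists did not pass. Tested genes without a count made up between 11.7% and 13.6% in tdTomato-negative and between 7.02% and 11.2% in tdTomato-positive libraries.

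**Figure D4:**
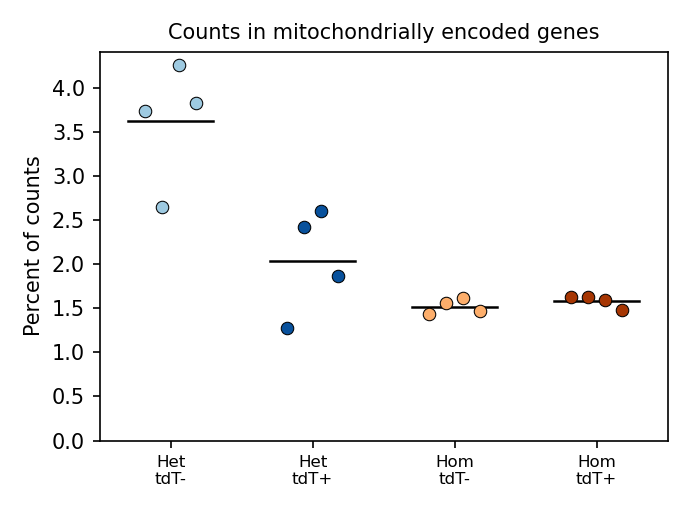
Percent of all counts in mitochondrially encoded genes (y axis), with 1 point per library, a black line at the mean of each group of 4 and the groups along the x axis (Het, heterozygous; Hom, homozygous; tdT, tdTomato). The heterozygous tdTomato-negative libraries lay between 2.65% and 4.26%, and the homozygous libraries between 1.44% and 1.63%.

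The last comparison asked whether the difference between tdTomato-positive and tdTomato-negative cells depended on genotype. The interaction test of edgeR called 13 genes, 8 higher and 5 lower in the homozygous minus the heterozygous difference, with 992 at an unadjusted p under 0.05. The interaction was positive for Fcmr (0.86, SE 0.15, adjusted p = 0.0368), mt-Nd2 (1.81), mt-Nd1 (1.38), Fcgrt (2.04), the cytoskeletal spectrin Sptan1 (1.33), Iglc1 (1.02) and H2-DMb1 (0.89). Plxnc1 (-2.49) and Itgax (-8.91, adjusted p = 7.4e-05) had negative values, but the Itgax value rests on 2 counts in heterozygous tdTomato-negative libraries. Zfp318 had an interaction of -0.12 (adjusted p = 0.998). Leaving out heterozygous tdTomato-negative library 1, 2, 3 or 4 gave 41, 28, 33 and 28 calls, and leaving out any 1 of the 8 homozygous libraries gave 1. Itgax was called in each of these leave-outs, but not with voom (adjusted p = 0.26).

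The interaction was negative for germinal center (median -0.97), marginal zone and B1 (-1.11), CD11c-positive T-bet-positive (-0.91) and G1/S genes (-0.58), none of which held with an estimated correlation. It was positive for mitochondrially encoded (1.24), nuclear complex I (0.21), ribosomal (0.24) and antigen presentation genes (0.25), which did not hold with it either. The camera adjusted p was 0.000257, 0.000257, 0.000478 and 0.00371 for the first 4 lists and 2.2e-14, 0.00376, 0.000257 and 0.0182 for the other 4. Over all genes, 2 mitochondrially encoded genes, 1 antigen presentation gene and 1 gene of the CD11c-positive T-bet-positive list were called. Adjusted over the list alone, 10 of 13 mitochondrially encoded genes passed, with 4 germinal center, 3 marginal zone and B1, 4 CD11c-positive T-bet-positive and 3 antigen presentation genes. With an estimated correlation the adjusted p was 0.0512 for CD11c-positive T-bet-positive, 0.0899 for marginal zone and B1, 0.137 for germinal center, 0.158 for mitochondrially encoded, 0.656 for G1/S genes and 0.727 for the other 3 lists. Across 10687 genes the tdTomato effects of the genotypes correlated with Pearson's r = -0.00954 and Spearman's rho = -0.0302, although genes are not independent replicates.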

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

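The tests of the mitochondrial transcripts other than the depth test, the tests of T cell and macrophage transcripts and the counts over other splits of the libraries were chosen only after the results were seen. Single libraries stood apart from the other 3 of their group in 11 of 151 groups tested, and chance alone gives about 1 in 20. Where the other 3 libraries had no count, a few counts force such a flag. This held for Itgax in heterozygous tdTomato-negative, Trac in homozygous tdTomato-positive and Trbc2 in both homozygous groups. The 11 of 151 are therefore not an excess over chance that can be relied on. Homozygous tdTomato-positive library 4 had the most genes with a count, 11684, and the lowest Cd55 of its group, 245 CPM. Heterozygous tdTomato-positive library 2 had the most counts per mapped read, 1.5, library 1 the most Ighm, 12200 CPM, and library 3 no Tbx21, 0 CPM. Heterozygous tdTomato-negative library 3 was the only 1 of its group with Itgax, 0.131 CPM, and library 4 had the lowest Trbc2, 21.7 CPM. Homozygous tdTomato-positive library 3 had the most Trac, 0.228 CPM, the most Trbc2, 1.37 CPM, and the lowest mt-Nd2, 315 CPM. Homozygous tdTomato-negative library 4 had the most Trbc2 of its group, 0.964 CPM.

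With all libraries, 9 named genes passed the interaction test for a tdTomato effect that differed between the genotypes. The values were 2.04 for Fcgrt, 1.81 for mt-Nd2, 1.38 for mt-Nd1, 1.33 for Sptan1, 1.02 for Iglc1, 0.89 for H2-DMb1, 0.86 for Fcmr, -2.49 for Plxnc1 and -8.91 for Itgax. Without any 1 of the 8 homozygous libraries, Itgax was the only gene called, so the calls of the other named genes were lost each time. Itgax rests on 2 counts in heterozygous tdTomato-negative libraries and was not called with voom. A replicate block left 2 calls. The list medians that differed were -0.974 for germinal center, -1.115 for marginal zone and B1, -0.911 for CD11c-positive T-bet-positive and -0.576 for G1/S genes. They were 0.212 for nuclear complex I, 1.239 for mitochondrially encoded, 0.238 for ribosomal and 0.247 for antigen presentation genes. None of these 8 lists held with an estimated correlation.

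Mitochondrially encoded transcripts were lower in heterozygous tdTomato-positive than tdTomato-negative libraries, with a median log2 fold change of -1.16 over 13 genes. No single heterozygous library set this, since the median stayed at or below -0.988 without any 1 of them. Depth stays open, since thinning to 8099655 counts left -1.13 but random thinning hardly moves genes with this many counts. An effect of tdTomato status in both genotypes is excluded, since the homozygous median stayed at or above 0.0486 in every leave-out, but chance stays open. The real split gave -1.13 and the highest of the other 34 splits 1.01 on the log2 scale, for a list picked among 47 because it fell. Fewer captured nuclear transcripts in heterozygous tdTomato-negative libraries stays open, since their lowest share of tested genes without a count lay 0.42 percentage points above the highest tdTomato-positive share. The rank correlation of that share with the mitochondrial share was 0.8 within the tdTomato-positive group, as capture would give, but -0.63 within the tdTomato-negative group. A state with more mitochondrial RNA in heterozygous tdTomato-negative cells may also be the source, as a hypothesis that these libraries cannot tell apart from a capture difference.

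Trac, Trbc2 and most tested macrophage transcripts were lower in the homozygous than in the heterozygous libraries. Erythroid and platelet markers did not pass as a list with all libraries, at a median of -2.96 in tdTomato-positive (camera adjusted p = 0.0507; 0.0258 in the 8-library fit) and -1.99 in tdTomato-negative cells (0.288). Of them, Hba-a1 was lower (log2 fold changes -2.80 and -3.19), calls lost in 6 and 2 of 8 leave-outs. Macrophage RNA stays open as a source, since 80% of 10 tested macrophage genes were lower in homozygous cells in both populations, with mean levels of 133 against 6.67 CPM for Hmox1, 103 against 6.52 for C1qb and 71.2 against 8.99 for Lyz2, but 5 of the 8 lower genes had been seen to fall before, and Adgre1 and Cst3 were higher. T cells stay open, since Cd3e, Cd3d and Cd3g together reached 5.98% of the level of Trac, 271 CPM, and Cd4 was not counted. Mean levels in heterozygous against homozygous libraries were 94.4 against 38.2 CPM for Lck, 2.11 against 0 for Cd8a and 1.09 against 0.367 for Thy1. The sort on B220 and NIP binding should remove both cell types, but its purity was not tested. For Trac itself, a homozygous table in which it was hardly counted stays open, since its 8 libraries held 2 Trac counts together. This does not account for the other T cell genes, since Trbc2, Cd3e, Cd3d and Cd3g together reached at most 9.93% of the lowest heterozygous library in any homozygous library. A biological difference between the genotypes in adhering or engulfed cells was not tested.

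Ribosomal genes were higher in homozygous libraries in both populations. Of 10000 lists matched on coding length and expression level, 100% had a lower median in each population. The matched lists had medians of 0.44 and 0.09 against 0.79 and 0.51. Matched genes differed from the ribosomal genes by a median of -0.372 log2 CPM and need not vary together. This leaves open how much of the rise these 2 traits explain. The scaling does not explain it, since the lowest median with another scaling was 92.6% of that with TMM. No single library does, since the lowest leave-out median was 67.1% of that of all libraries. A difference between the tables in library preparation or counting cannot be told apart from genotype. A higher ribosomal gene expression in homozygous cells may be the cause, as a hypothesis.

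Over all 35 splits of the compared libraries, chance cannot be excluded for the 114 genes of the heterozygous tdTomato comparison, since 2 splits gave as many or more and the highest other gave 268. For the 2 genes of the homozygous tdTomato comparison the highest other split gave 0, but 7 of the 8 leave-outs also gave 0, so this count does not exclude chance. For the 236 genes of that comparison in the 8-library fit, the highest other split gave 33. For the 1099 and 1121 genotype genes the highest other splits gave 2 and 1. For the 1182 and 724 genotype genes in the fits of the compared libraries they gave 0 and 0. In each of these the real split was the only 1 of 35 with as many genes, the smallest share that 35 splits can give. This argues against chance for the size of these counts, but not for any single gene. Differences between animals are not covered, since the labels do not identify the animals. For the 13 interaction genes 1 of 100 splits, the real one, gave as many, and the highest other gave 7.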

How the results depend on the processing

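The alternatives that use DESeq2 or voom on the compared libraries alone, and the genes named from the 8 homozygous libraries, were chosen only after the data were seen. The calls between genotypes depended least on the processing and those between tdTomato-positive and tdTomato-negative cells most. The heterozygous tdTomato count of 114 became 709 with DESeq2, 4 with voom, 23 with a replicate block, 0 in the 8-library fit, and there 38 with DESeq2 and 0 with voom. The homozygous count of 2 became 0 without a filter, 11 with DESeq2, 338 with voom, 0 with a replicate block, 236 in the 8-library fit, and there 357 with DESeq2 and 358 with voom. The genotype count in tdTomato-positive cells, 1099, became 1681 with DESeq2 on the libraries compared, and that in tdTomato-negative cells, 1121, became 724 in their fit. The interaction count of 13 became 194 with DESeq2, 7 with voom and 2 with a replicate block. With an estimated correlation the lists called were 0, 5, 3, 2 and 0, against 6, 9, 16, 17 and 8, and voom called 15 lists in the homozygous tdTomato comparison. The fits of the compared libraries use fewer samples and their own spread, and for the other alternatives the cause was not tested.

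Leaving out 1 library gave 123 to 488 heterozygous calls, 0 to 1 homozygous calls, 722 to 1120 and 608 to 1280 genotype calls and 1 to 41 interaction calls. Lists called ranged from 2 to 8, 7 to 9, 12 to 17, 15 to 18 and 6 to 11. The Zfp318 genotype change lay between -5.97 and -5.48 in tdTomato-positive and between -6.43 and -5.24 in tdTomato-negative cells. Its uncalled tdTomato effect lay between -0.39 and -0.06 in heterozygous and between -0.69 and 0.50 in homozygous cells, and the interaction between -0.47 and 0.71. The homozygous effect of Zfp318 turned positive with voom (0.30; 0.28 in the 8 libraries) and without tdTomato-negative library 1 (0.50; 0.52 in the 8-library fit, where the leave-outs ran from -0.66 to 0.52). Its interaction turned positive with voom (0.44), a replicate block (0.00306), and without heterozygous tdTomato-negative library 1 (0.06), homozygous tdTomato-negative library 1 (0.71) or homozygous tdTomato-positive library 3 (0.11) or 4 (0.07). The cause was not tested, but the homozygous libraries hold at most 5.8 CPM of Zfp318. The uncalled genotype change of Iglc2 in tdTomato-negative cells ran from -1.09 to 0.46 and turned positive without heterozygous library 1 (0.46), cause not tested. The correlation of the tdTomato effects stayed between -0.0434 and 0.00669 in the leave-outs.

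Libraries with the same replicate number did not deviate together, with correlations between -0.0086 and 0.087 within genotypes and between -0.029 and 0.02 across them. Of the numbers, 2 of 4, 1 of 4, 1 of 4 and 1 of 4 correlated best with themselves. The check found no pairing by number but cannot exclude one, since an effect of the animal could be small beside the spread between libraries. With the replicate block the genotype comparisons called 956 and 980 genes. In the heterozygous groups 823 and 500 genes with a mean of at least 5 CPM had no count in at least 1 library, against 2 and 2 in the homozygous groups, although the total counts of the heterozygous libraries were not lower.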

Other observations

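The antigen receptor genes, the hypothesis on receptors and the 8 genes named for it were chosen only after the results were seen, while the test on overlapping genes was written before. Homozygous libraries held more Iglv1 and Ighv1-72, which encode parts of the B1-8hi receptor against NP and NIP, and less Igkc. Iglv1, the lambda 1 variable segment, stood at 10200 ± 200 CPM in homozygous against 1240 ± 404 CPM in heterozygous tdTomato-positive cells (SD, n = 4 per group; log2 fold change 3.04, adjusted p = 5.4e-08). In tdTomato-negative cells it stood at 9650 ± 722 against 1950 ± 439 CPM (2.30, adjusted p = 1.6e-06). Ighv1-72, the V186.2 segment from which B1-8 derives, was higher as well, 265 ± 45.2 against 101 ± 13.4 CPM (1.40, adjusted p = 0.00246) and 314 ± 74 against 116 ± 64 CPM (1.44, adjusted p = 0.0025). Igkc, the kappa light chain, was lower, 1330 ± 99.7 against 7910 ± 3860 CPM (-2.57, adjusted p = 1.3e-05) and 1410 ± 95.1 against 12300 ± 5670 CPM (-3.12, adjusted p = 2.5e-06). Among IgG genes, Ighg3 rose in tdTomato-positive cells (1.25, adjusted p = 0.0337), but the call was lost in 7 of 8 leave-outs (adjusted p up to 0.1). It did not pass in tdTomato-negative cells (0.51, adjusted p = 0.456), and Ighg1 did not pass in tdTomato-positive cells (2.51, adjusted p = 0.0857) except without heterozygous tdTomato-positive library 1 (4.24, adjusted p = 0.000264). The lambda genes Iglc2 and Iglc3 did not pass, at 0.66 and 0.31 in tdTomato-positive and -0.79 and -0.25 in tdTomato-negative cells.

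Of 56 other tested heavy chain variable segments, 21 fell and 1 rose in homozygous tdTomato-positive cells, and 19 fell and none rose in tdTomato-negative cells. Of 84 kappa variable segments, 15 fell and 5 rose in tdTomato-positive cells, and 13 fell and none rose in tdTomato-negative cells. Variable segments resemble each other, so reads may be split between them in a way the counting decides. A hypothesis is that the heterozygous libraries held a larger share of cells with other antigen receptors. It stays open, since 78.6% of these 140 segments were lower in homozygous cells in both populations, against 33.5% of 10546 other genes, but this share restates the fall from which the hypothesis came. Segments also share reads and libraries, so they are not independent. The sort on NIP binding was the same per the labels, but the IgD gate may have kept unlike cells in the genotypes. A batch difference between the tables cannot be told apart from genotype.

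A separate hypothesis was that genes lower in homozygous cells in both populations arose from reads shared between overlapping genes and counted differently in the tables. Coding exons overlapped an exon of another gene on either strand in 21.1% of 284 such genes and in 20.6% of 9853 others. The ratio was 1.03 with an interval of 0.818 to 1.29, which argues against this hypothesis for overlaps so defined. Counts were over coding sequence, so overlaps with noncoding exons may share no counted reads, which weakens the test. Reads that map to several places were not covered.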
